A study of Mus musculus with 4 samples.

How the data were processed

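Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in mouse embryonic stem cells of strain 129S4/SvJae that overexpress a GFP fusion of H1foo, the linker histone variant of the oocyte. Linker histone H1 binds the nucleosome and the DNA that enters and leaves it. There were 4 libraries, 2 made with a rabbit polyclonal antibody against H1foo and 2 with AE4, a mouse monoclonal antibody used for the somatic H1 variants. Chromatin was cut by enzymatic digestion and libraries were made with a ligation kit, per the labels' protocols. Whether AE4 also binds H1foo is not given in the sources used here, and neither is the origin of the replicate libraries in separate cultures.

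Reads had been aligned with Bowtie 1.1.2 to the mouse genome build mm10, per the submitters' processing notes. Peaks had been called with MACS, per the file headers, which give no version. The authors deposited 1 peak list per antibody, each with chromosome, start, end, name and a score per peak. The score in the deposited lists is the caller's own value for each peak; its lowest value was 50 in both lists and its scale is not named in the files. It was used to rank and filter peaks within a list. Scores of the 2 lists are in places printed side by side or correlated across peaks, but are not read as amounts of binding. How the 2 libraries of an antibody were combined or selected for its list, and whether an input library served as control, are not given in the sources used here. The lists hold no value per library, so there was no replicate error, no correlation between replicates and no test of one antibody's libraries against the other's. The depth of the libraries is unknown, and the number of peaks a caller reports rises with depth. The intervals below therefore cover the placement of peaks along the genome in these 2 lists, and not the spread between cultures or libraries.

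Starts were converted to positions counted from 1, and starts below 0 were set to 0 before the conversion. Comparisons used the 21 assembled chromosomes (19 autosomes, X and Y). Overlap meant at least 1 bp in common. Its chance level came from 1000 rotations, in which all peaks of the other list on a chromosome were moved by a single random distance around that chromosome, so that widths and spacing were kept. A local version moved them by 100 kb to 1 Mb, which keeps the broad regional density as well. Rotation p-values are two-sided permutation p-values, and 0.002 is the smallest they can give. The 95% intervals came from 1000 bootstrap draws over blocks of 10 Mb, except for the chromosome ratios among the alternatives. Regional density was the number of peak centres in bins of 1 Mb, compared by Spearman's rho across bins. Bins are not independent replicates, and the chance level again came from rotations. Bins in gene density classes were taken from the autosomes without the first 3 Mb of each chromosome, which hold no sequence in this build.

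Gene positions were those of 21774 protein-coding genes in a table of NCBI RefSeq gene spans on GRCm38.p6, whose assembled chromosomes have the coordinates of mm10. Another 113 genes on scaffolds were left out. The table gives neither strand nor exons, so a start site could not be told from the other end of a gene. The planned classes of promoter, exon and intron were therefore replaced by the sequence within 2 kb of either gene boundary, the rest of the gene, and the rest of the genome, assigned by peak centre. A gene with a boundary peak is one with any part of a peak within 2 kb of either boundary. The planned measurements of base composition in peaks and of the Esrrb motif were not made, because no genome sequence was used here.

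The 16 gene lists, the main comparisons, their tests and the rule for named genes were fixed before the data were examined, apart from the replacements stated here. Gene boundaries thus stand in for the planned start sites in the tests and in the rule. For each list the number of genes with a boundary peak was set against 10000 random lists of the same size. Random genes were drawn from the same decile of gene density (genes in a window of 1 Mb) and the same tertile of gene length, in place of the planned matching on promoter GC content. The two-sided permutation p-values, of which 0.0002 is the smallest possible, were adjusted by the Benjamini-Hochberg method over the 32 tests. The difference between the antibodies per list was tested in the same way over 16 tests, a test added after the data were seen. No test per gene was made. Lists held 28 of 33 imprinted genes and 17 of 21 genes of the 2-cell stage. The imprinted Airn, Kcnq1ot1, Meg3, Nespas and Peg13 and the symbols Zscan4a, Zscan4e, Dux and Eif1ad8 had no match among the protein-coding genes of the table. The other lists matched in full.

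The genes named were chosen by rule. They were the members of the pluripotency, oocyte and linker histone lists with a boundary peak, the 10 genes with the highest-scoring boundary peak of each antibody, and the 10 genes of at least 20 kb with the most peaks of one antibody per 100 kb and no peak of the other. The fixed rule gave bins only in place of genes, where no annotation was at hand, but they were named here too. They were the 5 bins with the most peaks of each list and the 5 bins at either end of the ratio of shares among bins with at least 10 peaks. Members of other lists are named as examples chosen after their values were seen.

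Alternatives were other definitions of overlap, other nulls, other bin and window sizes, peak bp in place of peak number, the upper 50% of each list by score, H1foo thinned to the number of AE4 peaks by score, merged peaks, autosomes alone, unmatched random lists, and runs without chromosome 8. They used 200 moves, whose smallest p is 0.01. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlap counts were checked with bedtools 2.31.1. The tests were run on simulated data first. Of 40 rotated AE4 lists with no planted overlap 2 were called, and 5.12 points were recovered where an overlap of 5% of peaks was planted. These runs used fewer rotations than the main test. Rotated lists meet the rotation null by construction, so the runs check the code and not whether rotation suits the real lists. Of 200 random lists of 30 genes 6 were called for H1foo before adjustment. With 3 times the odds of a peak, 145 of 200 lists of 30 genes and 200 of 200 lists of 100 genes were called, also before adjustment, so a smaller excess in a list of 30 genes can be missed. After adjustment fewer would be called. Genes of the simulated lists were drawn from the whole genome, so these rates do not carry over to lists of clustered genes.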

Results

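Binding of the oocyte linker histone H1foo and of somatic H1 was mapped in the same mouse embryonic stem cells by ChIP-seq, with 2 libraries for each antibody. The data are 1 peak list for H1foo and 1 for AE4, an antibody used for somatic H1, in coordinates of mm10. The H1foo list held 97825 peaks with a median width of 560 bp, which covered 65.5 Mb or 2.40% of the assembled chromosomes. The AE4 list held 47493 peaks with a median width of 466 bp, which covered 25.8 Mb or 0.945%. H1foo thus had 2.06 times as many peaks and 2.54 times as many covered bases as AE4. The read depth behind each list is unknown, so that ratio is not a measure of the amount of either protein on chromatin. Scores are the authors' values and had a median of 73.2 in the H1foo list and 63.8 in the AE4 list. Neither list has replicate values.

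The first comparison asked whether H1foo and AE4 peaks lie at the same places. Whether AE4 also binds the overexpressed H1foo, and whether an input library served as control, are not given in the sources used here. A shared peak is therefore not read as binding of both proteins. Background common to both antibodies' libraries was not tested, here or in the comparisons below. Of the AE4 peaks on assembled chromosomes, 24297 of 47449 or 51.2% overlapped an H1foo peak (block bootstrap 95% interval 47.8 to 54.2%). Of the H1foo peaks, 23559 of 97795 or 24.1% overlapped an AE4 peak (22.3 to 26.1%), and 74236 did not. Rotated lists gave 5.81% and 2.85%, so the overlap was 8.81-fold and 8.44-fold above chance (two-sided permutation p = 0.002 for both, the smallest the rotations can give). Against peaks moved by no more than 1 Mb, which keep the regional density, the overlap was 3.17-fold and 3.06-fold above chance with the same p.

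Peaks with high scores were shared more often. The share of AE4 peaks that overlapped an H1foo peak was 34.0% in the lowest decile of AE4 scores (31.5 to 36.3%) and 87.6% in the highest (85.1 to 89.8%). For H1foo peaks it was 10.7% in the lowest decile (9.86 to 11.6%) and 60.3% in the highest (56.5 to 64.5%). Peaks with high scores were also wider, and the overlap expected by chance rose with the score. In the lowest and highest decile, lists moved by no more than 1 Mb gave 11.8% and 28.7% for AE4 and 4.94% and 17.7% for H1foo. The fold over this chance level went from 2.88 to 3.06 for AE4, with its highest value of 3.44 in decile 8, and from 2.17 to 3.41 for H1foo. The AE4 fold cannot exceed 3.49 in the highest decile, where all peaks would be shared. In points above this chance level, the shares went from 22.2 to 58.9 for AE4 and from 5.79 to 42.6 for H1foo. With each peak cut to the 200 bp around its centre, the shares were 22.3% and 49.6% for AE4 and 8.46% and 27.0% for H1foo. Shared peaks had a median width of 534 bp against 421 bp for unshared ones in the AE4 list, and 706 bp against 528 bp in the H1foo list. Shared AE4 peaks had a median score of 72.1 and unshared ones 59.3, and shared H1foo peaks had 98.3 against 68.5. Among the 100 highest-scoring peaks, 99 of H1foo and 97 of AE4 overlapped the other list. Across 21927 H1foo peaks that overlapped exactly 1 AE4 peak, the scores of the 2 overlapping peaks had a Spearman's rho of 0.28. An AE4 peak can enter more than 1 of these pairs, and peaks are not independent replicates.

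**Figure D1:**
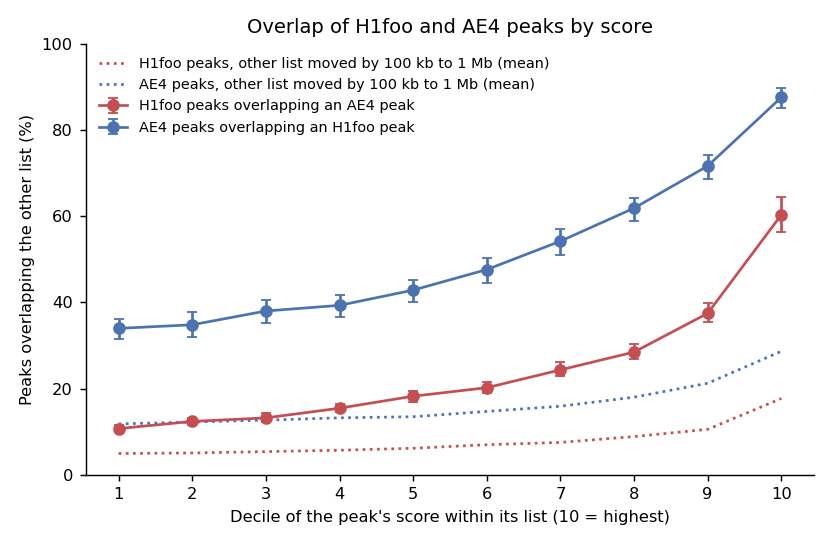
Share of peaks (%) that overlap a peak of the other list, by decile of the peak's score within its own list; bars are block bootstrap 95% intervals and dotted lines the means per decile with the other list moved by 100 kb to 1 Mb. In the AE4 list the share goes from 34.0% in the lowest decile to 87.6% in the highest, and in the H1foo list from 10.7% to 60.3%.

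High scores lay in clusters, some of them in both lists. On chromosome 6, in the interval between the genes Hrh1 and Atg7, the span 114498455 to 114630414 held 21 of the 100 highest H1foo scores, among them the highest of the list at 2839. The AE4 list had 13 of its 100 highest scores in 114498723 to 114630918 on the same chromosome. The span 20069192 to 20707178 of chromosome 8 held 17 of the 100 highest AE4 scores, and 15 of these 17 peaks overlapped an H1foo peak.

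Peak density differed widely between chromosomes. Chromosome 8 had the highest density in both lists, with 81.1 H1foo and 56.0 AE4 peaks per Mb. This was 2.31 times the median of the other 18 autosomes for H1foo and 3.45 times for AE4. The next densest chromosome was 11, with 78.8 H1foo and 33.7 AE4 peaks per Mb. Chromosome 8 also held 54 of the 100 highest H1foo scores and 59 of the 100 highest AE4 scores. Counted in bp of peak, the ratio for chromosome 8 was 3.13 for H1foo and 5.004 for AE4. Its share of AE4 peaks, 15.3%, was 1.42 times its share of H1foo peaks, 10.7%, while this ratio lay between 0.8002 and 1.14 on the other 18 autosomes.

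The sex chromosomes had few peaks. Chromosome X carried 164 H1foo and 215 AE4 peaks, or 0.959 and 1.26 per Mb, so the median of the autosomes other than 8 was 36.6 times as dense for H1foo and 12.9 times for AE4. The autosome with the lowest density, chromosome 14, was still 17.96 times as dense as X for H1foo and 6.68 times for AE4. Chromosome 18, with 5.63 protein-coding genes per Mb as on X, had 23.5 H1foo and 10.5 AE4 peaks per Mb. Chromosome Y had 14 H1foo and 28 AE4 peaks. These are descriptions of 2 lists, since chromosomes are not replicates.

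**Figure D2:**
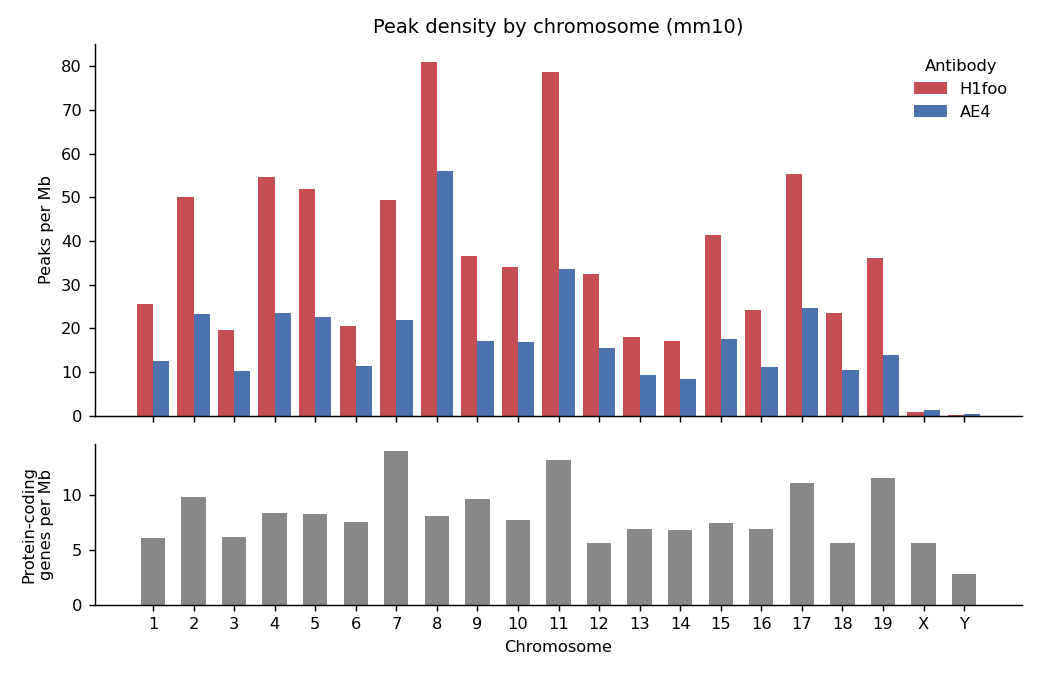
Peaks per Mb on each mm10 chromosome for the H1foo and AE4 lists (upper panel, bars) and protein-coding genes per Mb (lower panel). Chromosome 8 stands at 81.1 H1foo and 56.0 AE4 peaks per Mb, and chromosome X at 0.959 and 1.26.

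In bins of 1 Mb the peak numbers of the 2 antibodies went up and down together. The numbers of H1foo and AE4 peaks in 2737 bins had a Spearman's rho of 0.914, against a mean of 0.195 for rotated lists (two-sided permutation p = 0.002, adjusted p = 0.002 over 3 relations). Both followed genes, with a rho to the number of protein-coding genes of 0.702 for H1foo and 0.645 for AE4 (adjusted p = 0.002 for each). Rotation breaks the relation of the moved list to genes. The p for H1foo with AE4 therefore does not show a relation beyond their common relation to gene density. The 447 bins with 15 or more genes made up 18.5% of bins and held 55.1% of H1foo peaks and 52.1% of AE4 peaks. They had 120.2 H1foo and 55.0 AE4 peaks per Mb. The 273 bins without genes had 1.63 H1foo and 2.40 AE4 peaks per Mb.

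The bin with the most H1foo peaks was 80 to 81 Mb of chromosome 10, with 466 H1foo and 225 AE4 peaks and 54 genes that include Tcf3, Dot1l and Mbd3. The bin at 117 to 118 Mb of chromosome 11, with Socs3 and Birc5, had 430 and 175. The remaining bins of the H1foo top 5 ran from 120 to 123 Mb of chromosome 8, with 414, 426 and 448 H1foo peaks. The AE4 top 5 lay wholly on chromosome 8, with 361 AE4 peaks at 120 to 121 Mb, 323 at 70 to 71 Mb, 317 at 122 to 123 Mb, 288 at 121 to 122 Mb and 266 at 123 to 124 Mb. At the other end, the bin at 98 to 99 Mb of chromosome 2, which has no protein-coding gene, held 10 AE4 peaks and 1 H1foo peak. The others at that end of the ratio were 159 to 160 Mb of chromosome 3, with Rpe65 and Wls (13 AE4 and 2 H1foo peaks), 11 to 12 Mb of chromosome 6, with Ndufa4 (9 and 2), 63 to 64 Mb of chromosome 12, without a gene (8 and 2), and 90 to 91 Mb of chromosome 18, with Tmx3 (12 and 3). The bins with 13 H1foo peaks and 0 AE4 peaks were 20 to 21 Mb of chromosome 13, with Elmo1 and Aoah, and 71 to 72 Mb of chromosome 11, with Nlrp1a and Nlrp1b. Next to them at the H1foo end, with 12 H1foo peaks and 1 AE4 peak each, were 37 to 38 Mb of chromosome 5 with Msx1, 49 to 50 Mb of chromosome 9 with Drd2 and Ncam1, and 53 to 54 Mb of chromosome 3 with Frem2.

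The next comparison placed the peaks relative to genes. Within 2 kb of a gene boundary lay 17.2% of H1foo peaks (16.1 to 18.3%) and 12.8% of AE4 peaks (11.9 to 13.8%). The difference of 4.33 points had a block bootstrap 95% interval of 3.89 to 4.82. These shares were 2.81-fold and 2.14-fold above rotated lists (permutation p = 0.002 for each, adjusted p = 0.002). Against local moves the folds were 1.499 for H1foo and 1.17 for AE4, with the same p. Deeper inside genes lay 53.7% of H1foo and 55.3% of AE4 peaks, 1.43-fold and 1.48-fold above rotated lists, and outside genes lay 29.1% and 31.9%, below the 56.5% and 56.7% of rotated lists. Against local moves the folds deeper inside genes were 1.14 for H1foo and 1.20 for AE4, and the shares expected outside genes were 41.3% and 42.9%. For AE4 the local fold was thus no higher at boundaries than deeper inside genes.

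H1foo density was highest just inside genes. It was 27.1 peaks per Mb at 20 to 50 kb outside genes, 91.5 in the 500 bp outside a boundary and 157.4 at 500 to 1000 bp inside. AE4 density was 13.5 at 20 to 50 kb outside, 27.6 in the 500 bp outside, and reached 59.0 at 2 to 5 kb inside. The ratio of H1foo to AE4 density was 2.01 at 20 to 50 kb outside and 2.05 at 20 to 50 kb inside. It was 3.32 in the 500 bp outside a boundary and 3.39 in the 500 bp inside it.

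**Figure D3:**
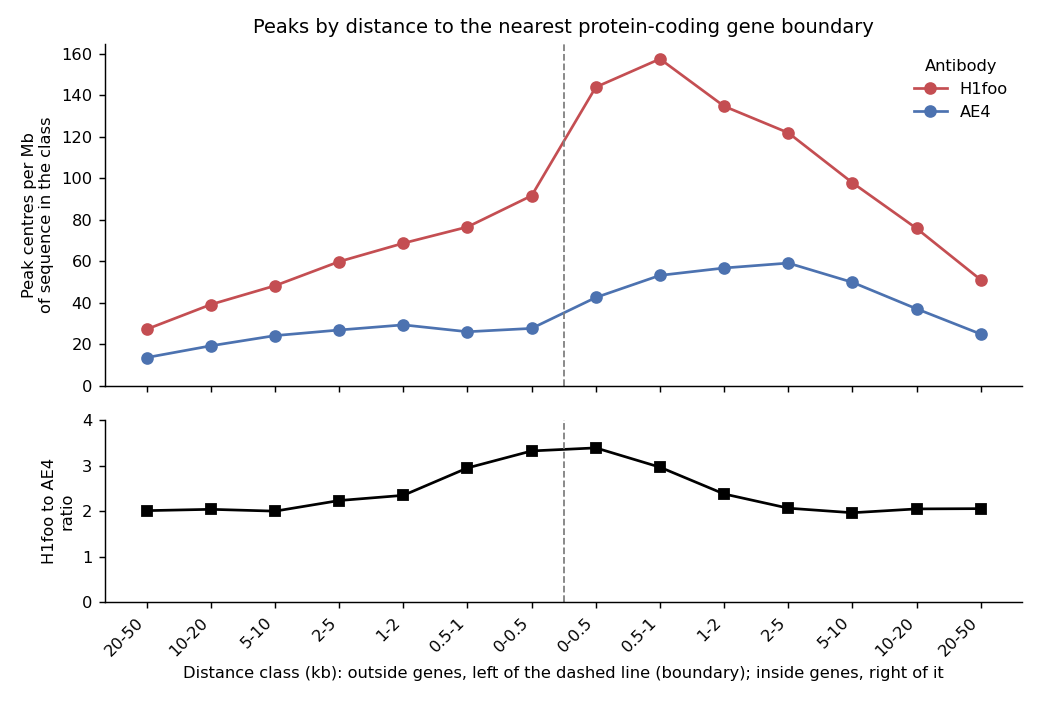
Peak centres per Mb of sequence in each class of distance (kb) to the nearest protein-coding gene boundary for H1foo and AE4 (upper panel), and the ratio of the 2 densities (lower panel); the dashed line is the boundary, with outside on the left and inside on the right. The ratio is 3.32 and 3.39 in the classes on either side of the boundary and 2.01 to 2.05 at 20 to 50 kb.

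By gene, 9773 of 21774 protein-coding genes (44.9%) had a boundary peak of H1foo and 5255 (24.1%) one of AE4. Both were present at 4694 genes, H1foo alone at 5079, AE4 alone at 561 and neither at 11440. Matched random draws gave 2878 genes with both (2823 to 2935 across draws), so the observed number was 1.63 times chance. The draws took genes as independent, although neighbouring genes can share a peak, so this range may be too narrow. It is not a block bootstrap interval.

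The genes with the highest-scoring H1foo boundary peaks were C130050O18Rik on chromosome 5 (peak at 139402341 to 139408537, score 1693) and Comp on chromosome 8, a cartilage matrix gene (70380961 to 70387685, score 1626). Tppp3, Carmil2, Tcf25, Slc7a5 (an amino acid transporter) and Lsm4 followed on chromosome 8, with scores of 1449, 1297, 1283, 1229 and 1195. The others were Myo15b on chromosome 11 with 1233, and LOC100504180 and Duxf3 at 58 Mb of chromosome 10 with 1222 and 1140. Each of these 10 peaks overlapped at least 1 AE4 peak. For AE4 the genes were Gm21119 on chromosome 8 (score 1152), Sfi1 on chromosome 11 (760.8), Duxf3 (738.7), Ticam1 on chromosome 17 (732.0), LOC100504180 (677.1), Gm51573 (670.3), Ripor1 (664.1), Gm51572 (593.1), Gm11127 (586.7) and Cope (581.6). Each of those peaks overlapped an H1foo peak. Some of the peaks in the 2 rankings were also in the window of other genes, so they are not peaks of the named gene alone. Examples are Comp with Crtc1, Tppp3 with Zdhhc1, Myo15b with Recql5 and Smim5, and Cope with Ddx49. The Tppp3 peak lay outside Tppp3 itself. Duxf3 and several of the predicted Gm genes belong to families with near-identical copies, where the placement of reads is uncertain. No filter for regions of artefact signal was applied here to any gene or bin named.

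Of 10008 genes of at least 20 kb, 1554 had H1foo peaks and no AE4 peak, and 596 had AE4 peaks and no H1foo peak. The densest with H1foo alone was Tor3a on chromosome 1, with 10 peaks or 48.3 per 100 kb. It was followed by Acp7 (41.7), Foxo6 (39.6), Tex45 (39.1), Dlg4, which encodes a postsynaptic scaffold (38.8), 1700008O03Rik (35.1), the cytidine deaminase gene Apobec3 (34.4), Sema7a (34.4), Anapc15 (34.1) and Chst5 (33.2). The densest with AE4 alone was Lsmem1 on chromosome 12, with 3 peaks or 13.1 per 100 kb. The others were Atp6ap1l (9.13), Fam71f1 (8.87), Ssr1 (8.77), Krba1 (7.93), 2610301B20Rik (7.88), Pon1 (7.72), Yipf7 (7.70), Gm42346 (7.69) and Phgdh, of serine synthesis (7.46), each with 2 or 3 peaks. With 2 lists of different length, the absence of a peak is not a measured absence of binding.

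The last comparison asked which gene groups carry peaks of either antibody at their boundaries. Olfactory receptor genes had a boundary peak at 33 of 1105 for H1foo and 21 of 1105 for AE4, where matched random lists had 546 and 340.5 (adjusted permutation p = 0.00064 for both). Vomeronasal receptor genes had 2 of 350 for each antibody, against 154.1 and 85.9 (adjusted permutation p = 0.00064). Core histone genes had 5 of 59 for H1foo and 0 of 59 for AE4, against 31.0 and 19.9 (adjusted permutation p = 0.00064 for both). Keratin and keratin-associated genes had 28 and 9 of 109, against 60.2 and 38.4 (adjusted permutation p = 0.00064), and Zfp zinc finger genes 188 and 83 of 394, against 219 and 123.3 (adjusted permutation p = 0.0037 and 0.00064). In all, 5 of 16 lists were below random for H1foo and 8 for AE4, and none was above after adjustment, with 6 and 8 lists at an unadjusted p under 0.05. Members of these families lie in clusters and some are near-identical, so they are not independent and reads at some are of uncertain placement. Clustered members also count toward each other's gene density, on which the random genes were matched. For Zfp genes the H1foo share was 47.7%, above the 44.9% of all protein-coding genes but below the 55.6% of matched lists. The AE4 share was 21.1%, below both the 24.1% of all genes and the 31.3% of matched lists. When peaks were rotated with the genes kept in place, the receptor families stayed below chance in both lists (permutation p = 0.01), while Zfp genes turned to above chance in both, at ratios of 2.35 for H1foo and 1.61 for AE4 (permutation p = 0.01 for each). The calls for core histones and keratins were lost, with ratios of 1.08 and 1.32 for H1foo (permutation p = 0.85 and 0.65) and, for AE4, 0 (no peak within 2 kb of a boundary of any core histone gene) and 0.719 (permutation p = 0.6 and 0.94). The H1foo call for Zfp genes was also lost with a window of 5 kb, over whole genes, and with random lists unmatched or matched on gene density alone (adjusted permutation p = 0.069, 0.061, 0.43 and 0.49), and the AE4 call with unmatched lists (adjusted permutation p = 0.31).

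AE4 was below random at 3 further lists. Hox genes had 1 of 39 with an AE4 peak, Hoxd4, against 9.08 (adjusted permutation p = 0.0023), ribosomal protein genes 8 of 80 against 17.7 (adjusted permutation p = 0.022), and clustered protocadherin genes 4 of 57 against 21.2 (adjusted permutation p = 0.00064). H1foo peaks lay at 11 of 39 Hox genes, 35 of 80 ribosomal protein genes such as Rpl18 (score 415.1) and Rpl10a (330.6), and 36 of 57 protocadherin genes, where random lists had 16.4, 30.9 and 38.5 (adjusted permutation p = 0.22, 0.54 and 0.67). The peaks with these scores at Rpl18 and Rpl10a lay outside the genes, more than 1 kb from them. The difference between the antibodies was 33.8 points for ribosomal protein genes against 16.4 in random lists (adjusted permutation p = 0.0032) and 56.1 points for protocadherin genes against 30.7 (adjusted permutation p = 0.0011). For Hox genes it was 25.6 against 18.8 (adjusted permutation p = 0.69). For olfactory and vomeronasal receptors it was 1.09 and 0 points against 18.6 and 19.5, which is set by the near absence of peaks in both lists and is not read as a difference between the antibodies. A single H1foo peak at 37842406 to 37844245 of chromosome 18 lay at the shared end of 21 of the protocadherin genes, which stand in 1 bin of 1 Mb. The protocadherin difference lost its call with a window of 1 kb (adjusted permutation p = 0.36), as did that of ribosomal protein genes (adjusted permutation p = 0.23). With unmatched random lists, the upper 50% of scores or matching on gene density alone, the ribosomal difference was not called (adjusted permutation p = 0.059, 0.12 and 0.097). The AE4 calls for Hox, ribosomal protein and protocadherin genes were lost with peaks rotated (ratios of 0.203, 0.931 and 1.12, permutation p = 0.45, 1 and 0.54), and the ribosomal call also with a window of 5 kb (adjusted permutation p = 1). H1foo itself was called below random at Hox genes in the upper 50% of scores and with matching on gene density alone (adjusted permutation p = 0.0043 and 0.023), above random at ribosomal protein genes with a window of 5 kb (49 genes, adjusted permutation p = 0.011), and above random at protocadherin genes with unmatched lists (adjusted permutation p = 0.02).

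Pluripotency genes had an H1foo boundary peak at 16 of 30, against 10.1 in random lists (6 to 15), which missed the adjusted threshold (p = 0.027, adjusted permutation p = 0.061, permutation test). The 16 were Nanog, Pou5f1, Esrrb, Prdm14, Tfcp2l1, Sall4, Klf2, Tbx3, Lin28a, Utf1, Fgf4, Gdf3, Dppa5a, Dnmt3l, Tcl1 and Rif1, and Sox2, Klf4 and Zfp42 were without one. The highest scores were at Dnmt3l, a cofactor of DNA methyltransferases (346.5, chromosome 10, 78040781 to 78044009), Klf2 (199.3) and Fgf4 (176.3). Nanog had 96.6 (chromosome 6, 122705670 to 122706470) and Pou5f1, which encodes Oct4, had 80.0 (chromosome 17, 35506252 to 35506820). Esrrb, an orphan nuclear receptor that the study group has linked to H1foo, spans 86361117 to 86521628 of chromosome 12 and held 45 H1foo and 11 AE4 peaks within 2 kb of the gene or inside it. Its highest boundary score was 123.4 for H1foo and 59.2 for AE4. AE4 boundary peaks lay at 5 of the 30, Sall4, Klf2, Dnmt3l, Esrrb and Tcl1, against 5.17 in random lists (adjusted permutation p = 1). The difference between the antibodies was 36.7 points against 16.8 in random lists (adjusted permutation p = 0.078). The H1foo call was made with a window of 5 kb (23 genes, adjusted permutation p = 0.00053), in the upper 50% of scores (13 genes, adjusted permutation p = 0.023), over whole genes (21 genes, adjusted permutation p = 0.017) and without chromosome 8 (15 genes, adjusted permutation p = 0.026). The difference was called in the same 4 settings (adjusted permutation p = 0.0008, 0.018, 0.009 and 0.031). The H1foo call was not made with a window of 1 kb (11 genes), with unmatched random lists or with matching on gene density alone (adjusted permutation p = 0.52, 0.56 and 0.11). Nor was that of the difference, which at 1 kb was 6.61 points beyond random (adjusted permutation p = 0.87, 0.2 and 0.099 in these 3 settings).

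Oocyte genes had an H1foo boundary peak at 11 of 26, against 12.2 (adjusted permutation p = 0.94). These were the zona pellucida genes Zp1, Zp2 and Zp3, the growth factor gene Gdf9 (score 383.5), Padi6 (359.7), Tle6, Ooep, Npm2, Mos, Nobox and Oog1. AE4 lay at 3 of 26, Padi6, Tle6 and Gdf9, against 6.76 (adjusted permutation p = 0.23). Among 11 linker histone genes, H1foo lay at Hils1 (195.4), H1f0 (63.4) and H1f7 (257.3), and AE4 at H1f7 (66.6), against 5.54 and 3.45 (adjusted permutation p = 0.36 and 0.35). The H1foo gene itself, H1f8 on chromosome 6, had no boundary peak of either antibody.

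The remaining lists did not pass the threshold for either antibody. Germline meiosis genes had 9 of 25 for H1foo and 4 for AE4 (adjusted permutation p = 0.46 and 0.59), imprinted genes 10 and 7 of 28 (adjusted permutation p = 1 and 0.54), and genes of the 2-cell stage 3 and 3 of 17 (adjusted permutation p = 0.41 and 1). Lineage regulators had 10 and 5 of 35 (adjusted permutation p = 0.98 and 1). Markers of fibroblast feeder cells, a cell type that a stem cell culture can hold, had 5 and 1 of 18 (adjusted permutation p = 1 and 0.54).

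**Figure D4:**
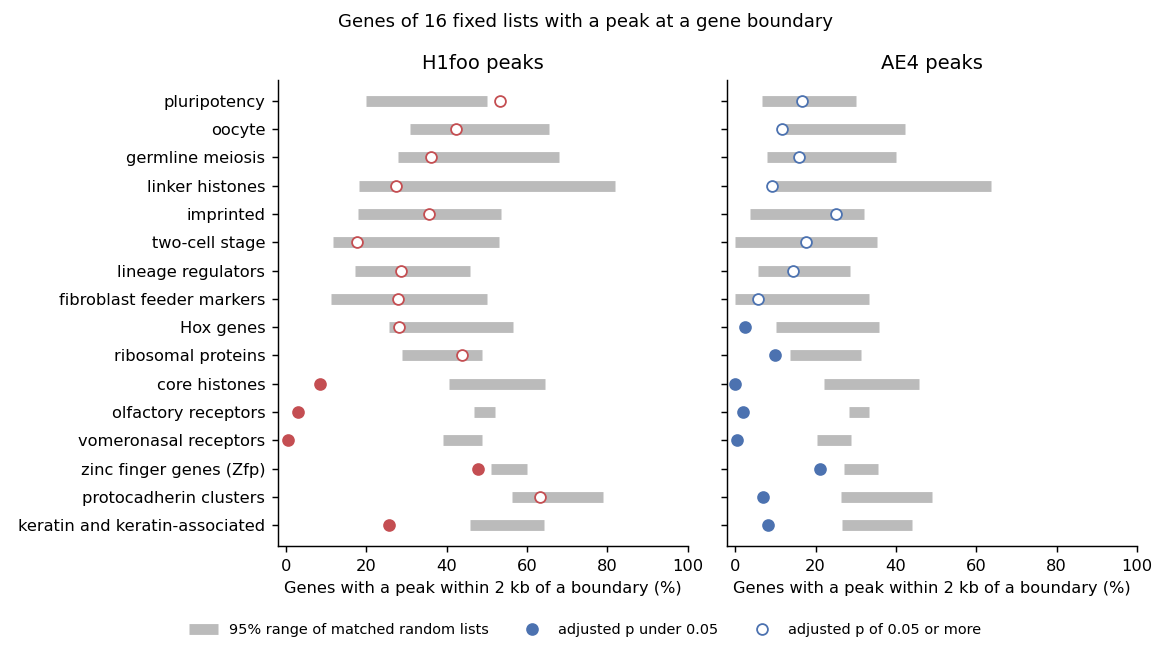
Genes (%) with a peak within 2 kb of a boundary in each of 16 lists for H1foo (left) and AE4 (right); points are the observed shares, filled where the adjusted p is under 0.05, and grey bars the 95% range of matched random lists. Olfactory receptors stand at 2.99% for H1foo and 1.90% for AE4, and pluripotency genes at 53.3% and 16.7%.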

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

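The tests of chromosomes 8 and X below were chosen only after the densities of these chromosomes had been seen.

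Peaks outside the assembled chromosomes entered no comparison, and were noted because scaffolds carried signal in both lists. There were 30 such H1foo peaks and 44 such AE4 peaks. Each list had its widest peak there, on an unplaced scaffold, at 31062 bp for H1foo and 23650 bp for AE4.

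Chromosome 8 was the densest autosome in both lists. Its gene density does not account for this as the whole cause, because its log2 residual from a fit of peak density on gene density over the other autosomes was 1.28 for H1foo and 1.85 for AE4, above the highest of the other 18 at 0.69 and 0.61. Without the 10 richest bins of each autosome, its ratio to the median of the others was 3.11 for H1foo and 4.05 for AE4. That cut also takes ordinary gene-rich bins from the other autosomes, which can raise the ratio, so it cannot decide whether a few dense clusters account for the density. Against bins of equal gene number, the H1foo ratios of its 10 Mb blocks ran from 0.560 to 4.73. The highest ratios of both lists were at 120 to 130 Mb. Extra copies of the whole chromosome in these cells, as could arise in culture, cannot be told apart from local enrichment, because 13 of 13 blocks of 10 Mb had more AE4 peaks than bins of equal gene number elsewhere but 10 of 13 had more H1foo peaks, and the AE4 ratios ran from 1.08 to 7.47 along the chromosome. The highest share of such blocks on another autosome was 7 of 10, on chromosome 17, for either antibody, so the H1foo count hardly sets chromosome 8 apart. No biological explanation was tested, and copy number was not measured here.

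Chromosome X was sparse in both lists. Its gene density does not account for this, because its log2 residual from the same fit was -4.52 for H1foo and -3.11 for AE4, below the lowest of the other autosomes at -0.73 and -0.78. A single copy of X, lower mapping of reads, and a lower amount of both linker histones there may each contribute and stay open, since the labels give neither the sex nor the karyotype of the cells. No biological explanation was tested.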

How the results depend on the processing

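The nulls with local moves or a start at 3 Mb, the runs without chromosome 8 or the first 3 Mb, the thinned list for chromosomes and positions, whole genes, matching on gene density alone, rotated peaks for gene lists, chance overlap and peak centres per score decile, and the tests of differences between the antibodies per gene list were added after the data were seen. Of 90 alternatives to the main results, 77 kept direction and side of the threshold, a value within the interval of the main one or, for a count of lists, one within 1.5 times the main count. Overlap ranged from 33.4 to 64.0% of AE4 peaks and 16.2 to 37.6% of H1foo peaks, rho across bins from 0.746 to 0.975, and the fold at gene boundaries from 1.497 to 3.20 for H1foo and 1.17 to 2.36 for AE4, all above chance. The boundary difference ranged from 3.38 to 6.84 points. The other 13 were ratios to the autosomal median and counts of lists. For chromosome 8 the H1foo ratio became 3.13 by bp, 2.95 in the upper 50% and 2.97 with thinning, and the AE4 ratio 5.004 by bp and 4.76 in the upper 50%. For X the H1foo ratio became 0.0219 in the upper 50% and 0.0215 with thinning, and the AE4 ratio 0.0605 in the upper 50%. The cause was not tested. Lists below random numbered 4 to 6 for H1foo and 7 to 8 for AE4. Lists above random for H1foo went from 0 to 2 with a window of 5 kb (pluripotency and ribosomal proteins), and to 1 each with unmatched random lists (protocadherins), the upper 50%, whole genes and without chromosome 8 (pluripotency in these 3).

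By list and antibody, 210 alternatives kept their call or stayed without one, 7 gained a call, 4 lost one and 3 turned. The ratio to random turned to 1.02 for ribosomal proteins with AE4 at 5 kb, and with unmatched lists to 1.06 for Zfp genes and 1.41 for protocadherins with H1foo. A turn was counted only where the main result or the alternative had a call. Ratios without a call also crossed 1, such as that of lineage regulators with H1foo, which ranged from 0.557 to 1.27. Against rotated peaks, which do not keep peaks in gene-rich regions, 4 of 13 calls held, 4 were lost and 5 turned, to 1.08 for core histones, 2.35 for Zfp genes and 1.32 for keratins with H1foo, and to 1.61 for Zfp genes and 1.12 for protocadherins with AE4, past the threshold for Zfp genes alone. That null expects fewer peaks at any gene by construction. For differences between the antibodies 99 kept their call or stayed without one, 7 gained a call, 5 lost one and 1 turned. Differences without a call also changed sign, such as that of imprinted genes, which ranged from -9.99 to 20.6 points beyond random. The keratin difference turned to 10.5 points above random at 5 kb and passed the threshold there. In the upper 50% the keratin difference was called in the other direction, at -23.4 points. The cause was not tested. Core histones were called at -14.8 in the upper 50% and at -19.5 with 1 kb. The other 4 gains were pluripotency genes.

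No paired analysis was possible because each peak list holds no value per library, and for the same reason no run without a library was made. Alternatives for base composition and for the Esrrb motif were not run, since no genome sequence was used here. Read depth is unknown and limits any statement on the number of peaks or on their absence.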

Other observations

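The 3 tests on bins without genes were chosen after that pattern was seen but before their own results were, while the cuts to 25%, the cuts of AE4 alone and the values on the span of chromosome 8 and on wide peaks were chosen after the data were seen.

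In the span of chromosome 8 with 17 of the 100 highest AE4 scores, the 15 overlapped peaks had a median H1foo score at percentile 99.2 of the H1foo list; with the 2 peaks without overlap set to 0, the median of all 17 was 97.8. In the complete lists, 33 H1foo peaks and 14 AE4 peaks were wider than 5 kb.

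Relative to H1foo, AE4 peaks were more frequent where genes are absent. In the 273 autosomal bins of 1 Mb without a protein-coding gene, the AE4 list had 656 peaks and the H1foo list 446, and the ratio of their shares was 3.04 (block bootstrap 95% interval 2.56 to 3.67). The ratio was 1.25 in bins with 1 to 4 genes (1.17 to 1.35), 1.00 with 5 to 14 genes (0.981 to 1.03) and 0.946 with 15 or more (0.926 to 0.965). A few bins with many AE4 peaks do not account for it, with 3.55 after the 10 richest were left out. AE4 calls near the score threshold stay open. With both lists cut alike the ratio was 3.44 in the upper 50% (2.60 to 4.58) and 3.59 in the upper 25% (2.41 to 5.56). The cut to 50% also took out gene-free H1foo peaks, keeping 29.4% of them against 33.2% of gene-free AE4 peaks. With AE4 alone cut the ratio was 2.02 (1.66 to 2.435) and 1.22 (0.902 to 1.62), with 66 gene-free AE4 peaks left at 25%. Gene-free peaks score low in both lists, so a cut of one list moves the ratio by construction. Neither kind of cut can therefore decide. The longer H1foo list stays open for that reason: thinning by score gave 5.23, but it left 126 of the 446 gene-free H1foo peaks and all AE4 peaks, so a rise was built in. Base composition, mapping of repeats and an unequal background in the 2 antibodies' libraries were not tested, so a preference of somatic H1 over H1foo for gene-free regions may be named only as a hypothesis.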
